A study of Mus musculus with 15 samples.

How the data were processed

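The series holds 15 mouse samples. Of these, 8 libraries came from DNase-seq, which maps stretches of chromatin open to nuclease cutting (DNase hypersensitive regions). One library each came from preSertoli cells of the fetal testis at embryonic day (E) 13.5 and at E15.5, embryonic stem (ES) cells, cultured skin fibroblasts, and adult brain, heart, kidney and liver. PreSertoli cells are the somatic cells of the fetal testis that enclose the germ cells, and they were sorted by flow cytometry. The DNase-seq labels name male embryos with a Sox9 fluorescent reporter, while the RNA-seq labels state the sorting alone. RNA-seq covered 3 pools of E15.5 preSertoli cells, drawn from about 165 embryos in all and with about equal numbers of cells, with 50 bp reads. H3K27ac ChIP-seq, which maps a histone mark of active promoters and enhancers, covered 2 pools of E13.5 preSertoli cells with 2 input controls. The labels call the RNA-seq and ChIP-seq libraries biological replicates, and they give 1 biological replicate per DNase-seq group.

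Per the labels' protocols, the preSertoli nuclei were cut by their own nucleases, because added enzyme degraded their DNA, whereas the other 6 cell types followed the standard DNase I protocol. Cell type and digestion method are therefore confounded between preSertoli cells and the rest. Per the submitters' processing notes, DNase-seq reads were handled with BWA 0.6.1-r104, SAMtools and bedtools, RNA-seq reads with CASAVA 1.8.2, Bowtie 0.12.7 and RSEM 1.2.0, and ChIP-seq reads with CASAVA 1.8.2, Bowtie and SICER. All used the mouse build mm9. The DNase peak caller, its threshold and the gene annotation are not given in the sources used here.

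Each deposited DNase list holds peaks called on 1 library, with the authors' score (highest 1000), the authors' signal height (highest 4.60) and the authors' −log10 p (from 1.3 to 16 in every list). These columns have no header, and their nature was read from the values. The score served only to rank peaks within a list, with ties ordered by signal height. The number of reads behind each DNase list is unknown. The H3K27ac file deposited by the authors is 1 list of domains for both ChIP libraries, without a value per domain, built from windows of 200 bp, and whether the libraries were pooled is not stated. The 2 input libraries have no separate values here.

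The deposited RNA-seq table gives square roots of scaled expected counts from RSEM, per the file headers and the labels. From the values, each library had been divided by its 75th percentile over rows above 0 in any library, and every squared value was a whole number of hundredths of a read (100% within a tolerance of 0.05 hundredths). Expected counts were recovered from these steps and converted to CPM, a count scaled to the total of its library. The planned units TPM, FPKM and RPKM were replaced by CPM, as laid down for files that give only counts. CPM is not divided by gene length, so differences in level between genes depend in part on transcript length. The 3 columns carry only a number, so the libraries are called 1, 2 and 3 after their columns. Of 28427 rows, 426 repeated another row of the same symbol exactly, and where a symbol occurred more than once its row of highest mean was kept, which left 27697 symbols. Genes with near-identical copies can share reads in the authors' counting, and values of such families are uncertain.

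DNase lists were compared by overlap of at least 1 bp. All 8 lists were merged with bedtools 2.31.1 into 1 set of regions, and a region was present in a library when a peak of that library lay in it. Such a region is called open there, and the absence of a called peak does not show that the chromatin was closed. A preSertoli-specific region was present at both stages and in none of the 6 other cell types. With 1 library per group there is no replicate check, and no p-value compares cell types. Spread was given as a jackknife standard error that leaves out 1 of the 21 chromosomes at a time, and shares carry Wilson 95% intervals, which cover counting error only. Overlap with H3K27ac was tested with a one-sided permutation test by 1000 circular shifts of the domains within each chromosome, whose smallest possible p is 0.001. Chance overlap of the 2 stages came from 100 shifts. The spread of shifts treats the chromosome as uniform and keeps only the spacing of the domains.

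A gene was called expressed at 1 CPM or more in all 3 libraries. Because there is a single RNA group, no differential test was made. Marker lists for cell types and functions, the planned tests and the rules for naming items were fixed before the data were examined, and tests chosen later are named where they are used. Each list's median of log2(CPM + 1) was placed among the medians of 10000 random lists of the same size, which describes these libraries and is not a test. Random lists were not matched on mean expression, since the level itself was the quantity described. Named items were the highest members of each list (up to 6 in the Sertoli list, 4 in others), the 10 genes with the highest mean that are neither mitochondrial nor ribosomal protein genes, the 5 genes above 10 CPM with the largest coefficient of variation, the 10 preSertoli-specific regions in an H3K27ac domain with the best rank at their weaker stage, and the 5 windows of 100 kb with the most such regions. Rows named only by a clone accession were passed over, a choice made after the data were seen. Other genes named in the text were chosen after their values were seen, and are members of the fixed lists.

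Functions were tested on simulated data. All of the 6000 planted regions received their planted membership (100%), and interval overlaps matched those of bedtools for 100% of 1000 intervals. The shift test gave p of 0.05 or less in 3.5% of 200 simulated sets without an excess, and in 100% of 200 sets with 20% of regions placed in domains. Regions and domains were placed there independently on a single chromosome. The rate therefore does not cover real regions and domains that cluster in the same parts of the genome. Of 100 random lists of 30 simulated genes, 7% lay above the 95th percentile. Of 28000 simulated expected counts, 100% were recovered within 0.005 in one simulated library and 99.9964% in another. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

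Alternatives covered the overlap required, the number of peaks per list, a stricter peak threshold, the stages and cell types required, the joining of near peaks, the chromosomes, the H3K27ac domains, the expression threshold and the replicates. An mm9 gene annotation and sequence were not used here, so the planned comparisons of regions near expressed genes and of motif frequencies were not run, and regions are given by position without gene context. Gene symbols were matched to older synonyms through a table of the later assembly GRCm38, used for names only.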

Results

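Chromatin accessibility was measured in 8 DNase-seq libraries, gene expression in 3 RNA-seq libraries of E15.5 preSertoli cells and H3K27ac in 2 ChIP-seq libraries of E13.5 preSertoli cells, with the aim of mapping regulatory elements in these cells. The E13.5 and E15.5 preSertoli lists held 88107 and 81467 DNase peaks, with median widths of 308 and 333 bp. ES cells had 96536 peaks, skin fibroblasts 62218, adult brain 63330, adult heart 70532, adult kidney 72370 and adult liver 72883. The covered length ran from 27.5 Mb in fibroblasts to 46.9 Mb in ES cells. The H3K27ac list held 28586 domains with a median width of 2200 bp, covering 71.1 Mb. The RNA-seq libraries held 47.8, 56.0 and 51.7 M expected counts. All positions are in mm9.

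The first comparison asked how far open chromatin was shared between preSertoli cells at E13.5 and E15.5. Of 109145 regions open at either stage, 56106 were open at both, a share of 51.4% (jackknife SE 0.346; Wilson interval 51.1 to 51.7). E13.5 preSertoli peaks overlapped an E15.5 peak in 66.5% of cases, against 3.05% ± 0.203 (SD of 100 shifts) expected from shifted positions, and 71.1% of E15.5 preSertoli peaks overlapped an E13.5 peak. Sharing rose with peak strength, since 89.1% of the higher-scoring E13.5 preSertoli peaks overlapped an E15.5 peak in an alternative added after the data were seen. The stages are represented by 1 library each, so a difference of stage is not separable from a difference of library or depth.

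The DNase lists of preSertoli cells at the 2 stages resembled each other more than either resembled the list of another cell type. Their base-pair Jaccard index, the shared length divided by the length in either list, was 0.559 (jackknife SE 0.00321), the highest of all 28 pairs. E13.5 preSertoli cells came next to ES cells (0.394, jackknife SE 0.00644), skin fibroblasts (0.389, SE 0.00419) and adult brain (0.383). The gap between ES cells and skin fibroblasts was below the SE of the first and above that of the second. No SE of that difference was computed. Adult kidney (0.361) and heart (0.341) followed, with adult liver last at 0.282. E15.5 preSertoli cells were closest to skin fibroblasts (0.384), brain (0.374) and ES cells (0.367), and again farthest from liver (0.280). Among the other cell types, adult kidney and liver (0.459, jackknife SE 0.00510), heart and kidney (0.458) and, in falling order, brain and heart and brain and kidney (0.445) were close to each other, and their order changed with the measure. ES cells and liver were the farthest apart (0.250). The order of the cell types next to preSertoli cells depended on the measure too. By the share of the smaller list overlapped, for E13.5 brain came first (59.6%), then skin fibroblasts (56.7%), heart (54.8%), kidney (53.8%) and ES cells (52.8%), with liver last (47.1%), and with the higher-scoring peaks skin fibroblasts (0.442) passed ES cells (0.438). For E15.5 brain also came first by that share (59.5%), then skin fibroblasts (56.8%), heart (55.4%) and ES cells (54.5%). The preSertoli pair ranked 1 of 28 with equal numbers of peaks, with the higher-scoring peaks and by the share of the smaller list. It was also the only pair in which both libraries were cut by the cells' own nucleases. Likeness of cell type and of digestion method therefore cannot be told apart.

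**Figure D1:**
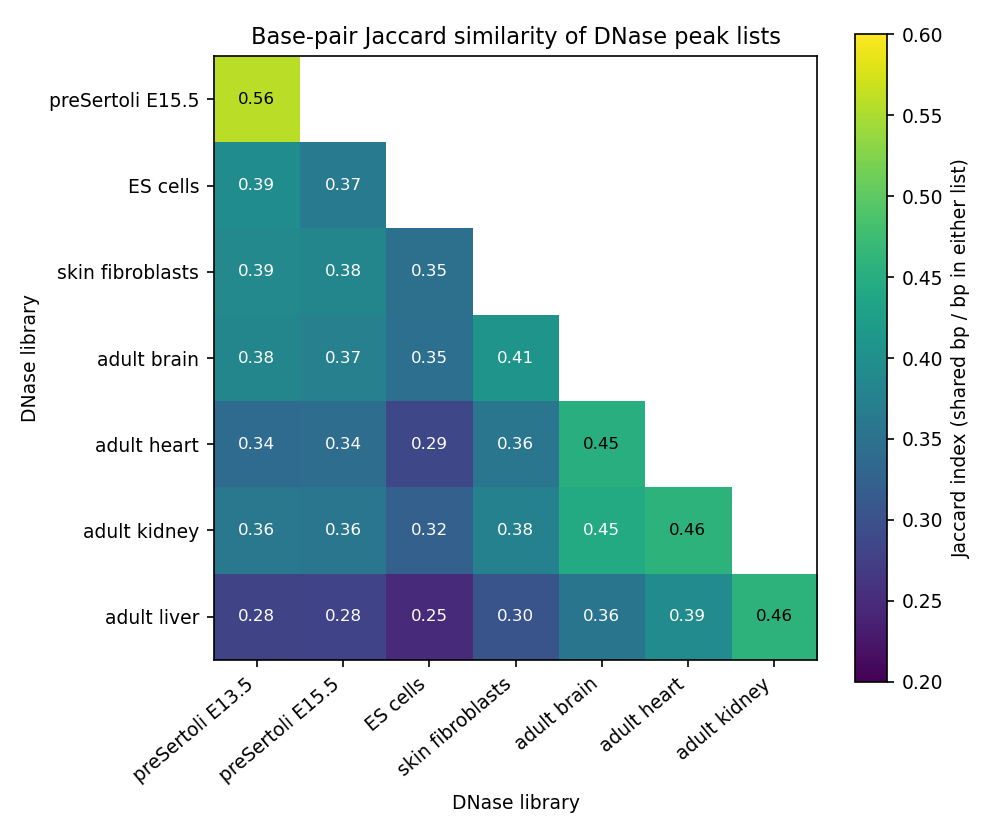
Base-pair Jaccard index for each pair of the 8 DNase-seq libraries, with cell colour and printed value giving the index (no unit). The pair of preSertoli stages stands at 0.559, and the lowest value, 0.250, belongs to ES cells and adult liver.

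The next comparison asked which regions were open in preSertoli cells and had no peak elsewhere. In the merged set, 10165 regions were present at both preSertoli stages and in none of the 6 other cell types, which is 4.28% of all regions. Another 20859 regions were open in all 8 lists, and 43760 were open in preSertoli cells at either stage and in some other cell types. Of the 55192 merged regions open at both preSertoli stages, 66.6% were also open in ES cells, 59.2% in kidney, 58.6% in heart, 57.7% in brain, 54.6% in skin fibroblasts and 51.8% in liver. ES cells were also the cell type that most often shared such a region alone, with 3368 regions against 1009 for heart and 444 for liver. The ES list was also the longest, and in the other direction ES cells came last: 39.3% of ES regions were open at both preSertoli stages, against 53.3% of brain, 51.8% of skin fibroblast, 48.6% of heart, 47.9% of kidney and 41.6% of liver regions.

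Regions open in a single other cell type numbered 36249 in ES cells, 18221 in liver, 14138 in skin fibroblasts, 12681 in heart, 11531 in kidney and 10994 in brain. The order below ES cells depended on list length. With equal numbers of peaks ES cells had 18453, skin fibroblasts 16169, liver 15725, brain 12458, heart 11074 and kidney 9709. These counts need only 1 library, whereas a preSertoli-specific region needs both stages. Of regions found in exactly 2 lists, the preSertoli pair had 10165, adult kidney with liver 5434, E13.5 preSertoli cells with ES cells 2816, E15.5 preSertoli cells with ES cells 1629 and heart with liver 1603, but the preSertoli pair alone joins lists of the same cell type. Requiring either stage in place of both gave 40256 preSertoli-specific regions, and using the higher-scoring part of each list gave 5133. The preSertoli libraries also differed from the rest in digestion method.

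PreSertoli-specific regions carried H3K27ac far more often than regions without a peak in preSertoli cells. At E13.5, 36.7% of the preSertoli-specific regions (3726 of 10165; jackknife SE 0.694) overlapped a preSertoli H3K27ac domain, against 6.44% (jackknife SE 0.114) of the 132737 regions found only in other cell types. The difference of 30.2 percentage points had a jackknife SE of 0.684. Regions open in all 8 lists overlapped most often, at 55.2%. Regions shared by preSertoli cells with some other cell types stood at 22.3%. There either stage sufficed, whereas preSertoli-specific regions needed both, so these classes differ in more than sharing. All regions open at both stages, specific or shared, stood at 40.2%. Those open at E13.5 and not E15.5 stood at 12.5%, and the reverse at 19.1%. Regions specific to brain stood at 4.04%, to skin fibroblasts at 5.67%, to liver at 5.86%, to kidney at 6.50%, to ES cells at 6.56% and to heart at 6.66%.

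Shifted domains overlapped 3.50% ± 0.237 (SD of 1000 shifts) of the preSertoli-specific regions and 3.28% ± 0.0986 of the regions found only in other cell types. Both observed shares lay above all shifts (one-sided permutation p = 0.001, the smallest the shifts allow), as did the share in each other class drawn. A comparison within bins of 10% of peak rank, with preSertoli-specific regions ranked by their E13.5 peak, was chosen after the data were seen. There, preSertoli-specific regions exceeded regions without a preSertoli peak by 28.8 to 31.6 points against each of the 6 other cell types. A gap is built into this comparison, because the other regions were chosen as lacking a peak in the cells where H3K27ac was measured. Among preSertoli-specific regions the share with H3K27ac went from 25.3% in the lowest bin of peak rank to 69.1% in the highest, the latter over 68 regions.

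**Figure D2:**
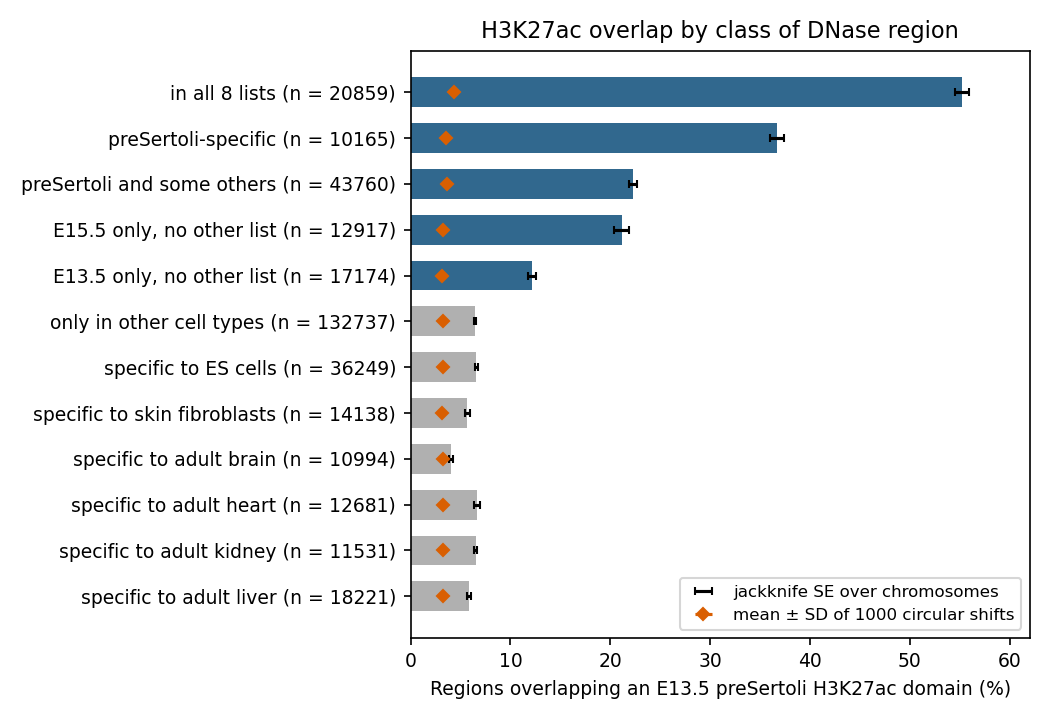
Share (%) of DNase regions overlapping an E13.5 preSertoli H3K27ac domain, by class of region with its number of regions. Bars give the observed share with the jackknife SE, diamonds the mean and SD of 1000 circular shifts, and preSertoli-specific regions (36.7%) lie between regions open in all 8 lists (55.2%) and those found only in other cell types (6.44%).

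**Figure D3:**
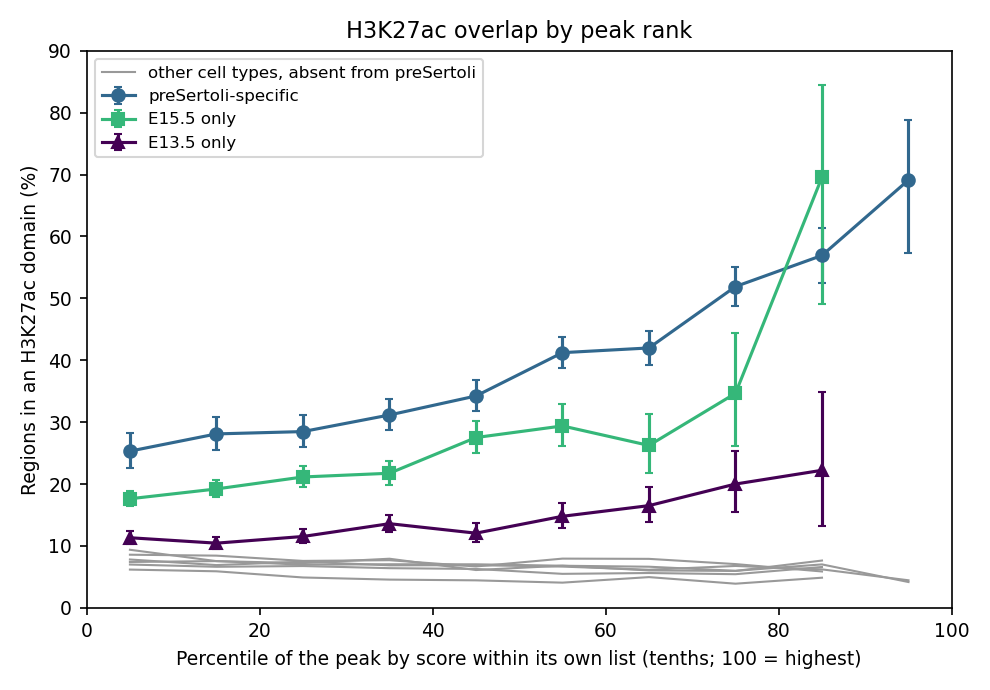
Share (%) of regions in an H3K27ac domain against the percentile of the peak within its own list, in bins of 10%. PreSertoli-specific regions are placed by their E13.5 peak. Each bin drawn held at least 20 regions. Bars are Wilson 95% intervals and grey lines are regions of the 6 other cell types without a preSertoli peak. PreSertoli-specific regions run from 25.3% to 69.1%, and E15.5-only regions lie above E13.5-only regions.

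Seen from the domains, the E13.5 preSertoli list reached 70.1% of the 28586 H3K27ac domains and the E15.5 list 68.7%. ES cells reached 54.4%, adult kidney 52.7%, adult heart 52.2%, skin fibroblasts 49.3%, adult liver 49.2% and adult brain 48.7%. These shares depended on list length. With equal numbers of peaks, an alternative added after the data were seen, ES cells, the longest list, fell to 49.8% and each preSertoli list to 64.8%. Skin fibroblasts, the shortest list, stayed at 49.3%. PreSertoli-specific regions lay in 3453 domains (12.1%), and 1513 domains (5.29%) held no other kind of DNase region. A further 5769 domains (20.2%) held no DNase region of any list, and their median width of 1400 bp was below the 2400 bp of domains with a region.

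Among preSertoli-specific regions with H3K27ac, the one with the best rank at its weaker stage lay on chromosome 7 from 124653421 to 124654279, within a domain of 6000 bp. It ranked 3964 of 88107 peaks at E13.5 and 3178 of 81467 at E15.5. The next were on chromosome 9 (115669241 to 115670409), chromosome 17 (24539041 to 24539794), chromosome 5 (109128696 to 109131028) and chromosome 17 (49611367 to 49612587). The list of 10 was completed by chromosome 9 (108019189 to 108020127), chromosome 14 (60296218 to 60297029), chromosome 5 (33357898 to 33358854), chromosome 9 (45136077 to 45137454) and chromosome 17 (7370343 to 7371113).

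The windows of 100 kb densest in preSertoli-specific regions lay on chromosome 5 (115000001 to 115100000), chromosome 1 (94900001 to 95000000) and chromosome 15 (83500001 to 83600000), with 9 regions each. Of these, 4 carried H3K27ac on chromosome 5 and 1 on each of the other chromosomes. Windows on chromosome 13 (51800001 to 51900000) and chromosome 14 (55500001 to 55600000) held 8 each, of which 6 and 4 carried H3K27ac, and were taken from 8 windows tied at that count, first by their number with H3K27ac. These were not all particular to preSertoli cells, since another cell type had 8 specific regions of its own in the chromosome 14 window, 6 in that on chromosome 13, 4 in those on chromosomes 1 and 15, and 3 in that on chromosome 5. Windows with 5 or more held 8.95% of the preSertoli-specific regions, the lowest share of the 7 cell types, below skin fibroblasts (9.63%), kidney (11.6%), brain (13.3%), heart (14.7%), liver (24.5%) and ES cells (37.0%). Liver and ES cells also had the most specific regions and preSertoli cells the fewest. The share was not adjusted for that number, so it does not show less clustering in preSertoli cells.

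Regions restricted to 1 stage made up the rest of the preSertoli set. In the merged set, 27957 regions were open at E13.5 and not E15.5, and 21726 at E15.5 and not E13.5. Of these, 17174 E13.5 regions and 12917 E15.5 regions were also absent from the 6 other cell types. The stage-restricted regions were weak, with 16.5% of the E13.5 ones and 11.6% of the E15.5 ones in the upper part of their own list split at the median, against 68.2% of regions open at both stages, counted 1 stage at a time. Regions specific to 1 other cell type were weak as well, from 16.6% in heart to 31.9% in liver.

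E15.5-only regions that no other list held overlapped the E13.5 H3K27ac domains in 21.1% of cases (jackknife SE 0.769), above the 12.2% (jackknife SE 0.411) of E13.5-only regions. The difference of E13.5-only minus E15.5-only regions was -8.97 points with a jackknife SE of 0.549. The E13.5 list was longer than the E15.5 list, and with equal numbers of peaks the restricted regions numbered 15909 at E13.5 and 16052 at E15.5.

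The X chromosome held 1.38% of E13.5 preSertoli peaks (Wilson interval up to 1.46) and 1.23% of E15.5 preSertoli peaks (1.16 to 1.31). In the other cell types it held 1.49% in skin fibroblasts and in heart, 1.54% in kidney, 1.65% in ES cells, 1.71% in brain and 1.79% in liver. The intervals of E15.5 preSertoli cells lay below those of all 6 other cell types, while the E13.5 interval overlapped those of skin fibroblasts, heart and kidney. With the higher-scoring peaks alone E13.5 preSertoli cells (1.52%) lay above heart (1.47%), kidney (1.47%) and liver (1.44%), so their place depended on the threshold, while E15.5 preSertoli cells (1.12%) stayed lowest. The labels give no sex for ES cells, fibroblasts or adult tissues, so X dosage was not controlled. Among these, Y peaks were listed for skin fibroblasts alone (115), so a Y chromosome was present in that library.

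RNA-seq asked which genes E15.5 preSertoli cells express. Among 27697 symbols, 13036 (47.1%) reached 1 CPM in all 3 libraries, 9810 reached a mean of 10 CPM, 2541 reached 100 and 56 reached 1000. Leaving out mitochondrial and ribosomal protein genes and 2 entries named by a clone accession, the highest were Eef1a1, a translation elongation factor, at 6106 ± 473 CPM (SD, n = 3, as for all values that follow), Sparc, a matrix glycoprotein, at 4390 ± 363 CPM, and the retinaldehyde dehydrogenase Aldh1a1 at 3295 ± 183 CPM. Hsp90ab1 (3180 ± 277 CPM), Clu (3172 ± 259 CPM), Hspa8 (2459 ± 175 CPM), the lipid desaturase Scd2 (2437 ± 121 CPM), Gstm2 (2316 ± 313 CPM), the lysosomal protease Ctsl (2168 ± 183 CPM) and Maged1 (2138 ± 115 CPM) followed. The libraries were close to each other, with Pearson correlations across expressed genes of 0.994 to 0.997 and a median coefficient of variation of 6.75%; genes are not independent replicates.

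Sertoli cell genes were high. Of 34 Sertoli markers, 33 were expressed, and the list median of 288 ± 5.70 CPM lay at the 100th percentile of random lists. The highest were Clu, Amh (anti-Müllerian hormone, which removes the female ducts) at 2048 ± 678 CPM, the protease inhibitor Serpine2 at 1119 ± 56.1 CPM, Gatm at 769 ± 63.9 CPM, the transcription factor Gata4 at 744 ± 17.7 CPM and Aard at 703 ± 21.6 CPM. The transcription factors Sox9 (259 ± 36.9 CPM), Sox8 (229 ± 13.7 CPM) and Dmrt1 (127 ± 0.900 CPM) were expressed as well. The labels of the DNase-seq samples, which name a Sox9 fluorescent reporter, describe the embryos as heterozygous for Sox9, and those of the RNA-seq samples do not say. Whether this goes with a change in Sox9 dosage was not examined here.

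The 11 secreted signals of Sertoli cells were all expressed, among them Inhbb (674 ± 41.8 CPM), Inha (475 ± 41.8 CPM) and Dhh (413 ± 38.7 CPM), the hedgehog ligand of the testis. All 12 basement membrane and junction genes were expressed with a list median of 319 ± 18.4 CPM, led by the gap junction gene Gja1 (1064 ± 61.2 CPM), Col4a1 (835 ± 29.4 CPM), Col4a2 (448 ± 33.7 CPM) and Nid1 (443 ± 7.48 CPM). All 10 cell cycle genes were expressed, with Ccnd2 at 894 ± 41.9 CPM, Mki67 at 593 ± 22.7 CPM and Top2a at 580.1 ± 25.1 CPM, while Ccnd1 stood at 6.98 ± 0.260 CPM.

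Markers of granulosa cells, the female counterpart, were low. Of 10, 4 were expressed, the highest being Esr2 at 4.62 ± 0.392 CPM, and Foxl2 stood at 0.0685 CPM. Germ cell markers were expressed in 10 of 14 cases at low levels, led by Tdrd9 (13.9 ± 0.695 CPM) and Ddx4 (12.3 ± 2.63 CPM). Endothelial (4 of 8), blood and macrophage (4 of 7), mesonephric epithelium (1 of 5) and peritubular myoid (4 of 4) lists had median levels of 1.63, 1.26, 0.895 and 7.04 CPM. The lists of the comparison tissues were low as well, with 1 of 7 ES cell, 1 of 5 liver, 1 of 6 kidney, 2 of 8 brain and 4 of 8 heart markers expressed. Tnni3 from the heart list (76.1 ± 2.49 CPM) and Mbp from the brain list (62.4 ± 6.63 CPM) were exceptions. Of 6 fibroblast markers 5 were expressed, with Col1a2 at 132 ± 34.3 CPM.

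Steroidogenic genes of fetal Leydig cells, which lie outside the cords, were high. Of 8 markers, 7 were expressed, with a list median of 139 ± 37.8 CPM at the 99.9th percentile of random lists. Cyp17a1 stood at 676 ± 145 CPM, Cyp11a1 at 381 ± 88.7 CPM, Star at 293 ± 85.2 CPM and Hsd3b1 at 223 ± 43.3 CPM. All 10 interstitial markers were expressed, with a median of 21.5 ± 3.31 CPM, led by Col3a1 (171 ± 45.4 CPM) and the hedgehog receptor Ptch1 (167 ± 9.76 CPM). Among expressed genes alone the interstitial list fell from the 94.0th percentile to the 23.6th, while the Leydig list kept its place.

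**Figure D4:**
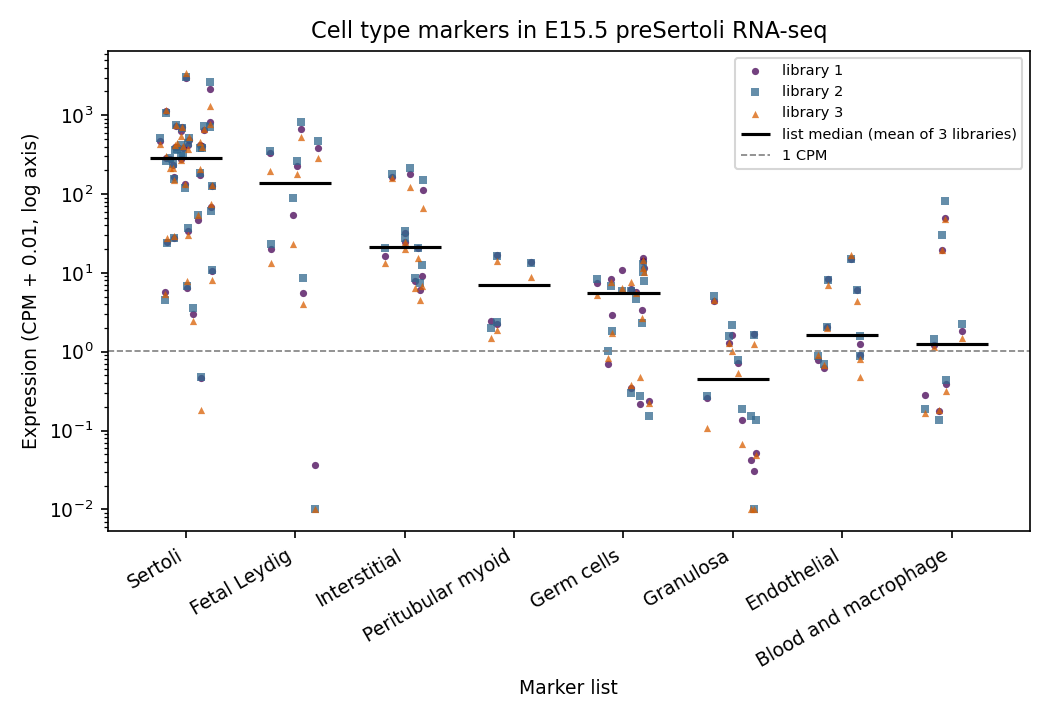
Expression (CPM + 0.01, log axis) of each marker gene in the 3 E15.5 preSertoli RNA-seq libraries, by marker list; black lines give list medians averaged over libraries and the dashed line 1 CPM. Sertoli markers have a median of 288 CPM, fetal Leydig markers 139 CPM and granulosa markers 0.436 CPM.

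The genes that varied most between libraries were Ftl2 (27.6 CPM, coefficient of variation 81.8%), H2afj (10.7 CPM, 67.1%), Dynlt1c (66.3 CPM, 66.9%), Fam176b (10.1 CPM, 59.9%) and the Leydig hormone Insl3 (54.9 CPM, 59.0%). Ftl2 and Dynlt1c have near-identical copies, so their values are uncertain. Library 3 was the lowest of the 3 for 16 of the 17 expressed Leydig and interstitial markers, against 37.5% of all expressed genes. Amh stood at 2167, 2660 and 1319 CPM in libraries 1, 2 and 3, and Sox9 at 278, 283 and 217 CPM.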

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

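Of 94 alternative values of the results that answer a comparison, 71 stayed within their limits and 23 moved. Counts had a wide limit, a fixed factor, so that 7009 preSertoli-specific regions with equal numbers of peaks, against 10165, counted as within it. The shares of regions at both stages and on the X had to stay within their Wilson interval, and the Jaccard index within its jackknife SE. H3K27ac shares had only to keep their direction and the side of 0.05 of their permutation p. The share of preSertoli regions open at both stages was 50.1% when 50% of the shorter peak had to overlap, 56.8% with the same number of peaks in every list (62218) and 59.9% with the higher-scoring part of each list. The Jaccard index of the 2 preSertoli stages became 0.574 with equal numbers and 0.587 with the higher-scoring part, and 71.1% of the smaller list was overlapped. Both settings keep fewer, stronger peaks. PreSertoli-specific regions numbered 5133 with the higher-scoring part and 40256 when either stage sufficed; leaving out any 1 of the other cell types gave 10609 (without liver) to 13533 (without ES cells). With the higher-scoring part, specific regions numbered 15886 in ES cells, 5301 in skin fibroblasts, 3779 in brain, 5406 in heart, 4530 in kidney and 9269 in liver, as fewer peaks entered; with equal numbers, ES cells had 18453. Regions open at E13.5 and not E15.5 numbered 15909 with equal numbers, 11618 with the higher-scoring part and 17174 when absence from the other cell types was added; the reverse numbered 8781 with the higher-scoring part and 12917 with that absence. The X share with the higher-scoring part was 1.52% at E13.5 and 1.12% at E15.5, and 1.05% of base pairs at E15.5; the cause was not tested. The share of preSertoli-specific regions with H3K27ac ran from 26.2% (wider domains alone) to 49.8% (higher-scoring part) over the settings tried. The one-sided permutation p was 0.005 in each, the smallest that 200 shifts allow. It was the same for regions found only in other cell types, so this p cannot show stability. Expressed genes numbered 10823 to 13995 over thresholds of 5 and 0.5 CPM, and 13097 to 13185 with 1 library left out. Restricted to expressed genes, the granulosa, germ cell, interstitial, myoid, endothelial, blood, heart and fibroblast lists fell to low percentiles, such as 1.27 for germ cells against 81.2 over all genes; lists with fewer than 3 expressed members were not run. No paired analysis was possible because the groups that share replicate numbers (RNA-seq, ChIP and input) were not compared with each other and the results come from no test between them. Not run, for want of an mm9 annotation, sequence or gene lengths in what was used here, were all alternatives for regions near expressed genes, for motifs and for length-matched random lists. Tests within bins of peak rank, counts of single peaks with a 1 bp overlap, domain coverage with fewer peaks and the higher-scoring E13.5 peaks against all E15.5 peaks were added after the data were seen. Unknown read depth of the DNase-seq libraries limits every count of regions.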

Other observations

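Transcription factor families of the preSertoli cells had few high members. Of 19 Sox genes, 10 were expressed, led by Sox9 (259 ± 36.9 CPM), Sox8 (229 ± 13.7 CPM), Sox12 (192 ± 13.3 CPM) and Sox4 (149.9 ± 26.6 CPM), while Sox2, a factor of ES cells, stood at 0.163 CPM. Of 6 Gata genes, Gata4 (744 ± 17.7 CPM) and Gata6 (73.3 ± 6.17 CPM) were well above Gata1 (2.20 CPM). Dmrt1 (127 ± 0.900 CPM) led 3 expressed members of 10 Dmrt genes, Six5 (63.7 ± 4.25 CPM) was the sole expressed member of its family of 6 and Lhx9 (8.26 ± 2.53 CPM) that of 8 Lhx genes. Of 44 Fox symbols, 18 were expressed, led by Foxp4 (206 ± 25.7 CPM) and Foxm1 (139 ± 12.1 CPM).

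Specific open regions were scarce on the X chromosome. Of 1343 X regions open at either preSertoli stage, 72 (5.36%; Wilson interval 4.28 to 6.70) were preSertoli-specific, against 9.75% (9.57 to 9.94) on the autosomes, although X and autosomal regions were open at both stages equally often (52.6% for each). The same direction was seen in brain (8.94% on the X, 18.6% on autosomes), heart (11.8% and 19.2%), kidney (10.8% and 17.0%) and skin fibroblasts (17.6% and 24.4%), whereas the intervals overlapped in ES cells (36.4% and 38.9%) and in liver (26.2% and 26.5%). Peaks on the Y chromosome were listed for E13.5 preSertoli cells (70), E15.5 preSertoli cells (61) and skin fibroblasts (115), and none for the other 5 libraries.

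The tests of the E15.5-only and library 3 patterns below, and the count of peak strength stage by stage, were chosen after the results were seen; the others were fixed before. Stage-restricted regions of preSertoli cells cannot be told apart from peaks near the calling threshold: 14.4% lay in the upper part of their own list. Regions specific to heart (16.6%), brain (19.9%), kidney (19.9%) and skin fibroblasts (21.5%) were nearly as weak. Those specific to ES cells (28.6%) and liver (31.9%) were less so. E15.5-only regions lay in E13.5 H3K27ac domains more often than E13.5-only regions. Within bins of peak rank the difference was 9.20 points (jackknife SE 0.592). These bins rank each peak within its own list, so a longer tail of weak E13.5 peaks would shift them. They therefore cannot decide on such a tail. With equal numbers of peaks in every list the difference was 9.90 points, so list length alone leaves it unexplained. With equal numbers of peaks the E13.5 list reached 0.014 points more of the domains than the E15.5 list (jackknife SE 0.269), against 70.1% and 68.7% for the whole lists of 88107 and 81467 peaks and 58.5% and 56.3% for their higher-scoring parts, where the E13.5 list is the longer. An exchange of the 2 stage labels therefore cannot be told apart from H3K27ac that precedes opening, and the second is untested. Nor can either be told apart from peaks near the calling threshold or a difference of library or depth. In the whole lists, 34.6% of E15.5 peaks lay in domains, against 31.5% of E13.5 peaks.

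PreSertoli-specific regions could in principle come from cutting by endogenous nucleases, which only the preSertoli libraries had. They carried H3K27ac 5.69 times as often as regions found only in other cell types. Those were chosen as lacking a peak in the cells where H3K27ac was measured, so the ratio was high by design. An effect of digestion therefore cannot be told apart from cell type. Shifted domains overlapped 3.50% of the specific regions against 36.7% observed, which argues only against cuts placed at random along the chromosomes. Regions found only in other cell types exceeded their shifts too (6.44% against 3.28%), so this comparison does not decide on digestion. Weak peaks cannot be told apart as a cause either: 61.0% had a peak in the upper part of a preSertoli list, a share raised by taking the better of 2 stages, and stage by stage 43.8% did, below the 68.2% of all regions open at both stages and above the 16.6% (heart) to 31.9% (liver) of regions specific to other cell types, which needed 1 list alone. Whether the specific regions are preSertoli regulatory elements stays open, since no preSertoli library cut with added DNase I was analysed here.

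Leydig and interstitial markers may reflect cells carried along in the sort, in amounts that differed between libraries. Library 3 was lowest for 16 of 17 expressed members, against 37.5% of all expressed genes. Their median log2 ratio was -0.56 against libraries 1 and 2. Library 2 was highest for all 17, against 30.2% of all expressed genes. The 32 expressed Sertoli markers other than Amh had a median of 0.06. Fewer Leydig and interstitial cells in library 3 would give this pattern, but the shift was broader. Blood and macrophage (-0.31), fibroblast (-0.31) and peritubular myoid markers (-0.29) were lower as well, with germ cell markers at -0.02. Ribosomal protein genes were higher in library 3, where 59 of 69 were highest (median 0.21). A change in interstitial cells alone leaves this unexplained. The share of all expressed genes highest in library 3 is not given here. Amh, a Sertoli gene, was also lower, at a log2 ratio of -0.87 against a spread of 0.174 (SD) among the other Sertoli markers, which such a change does not account for. Sox9 (-0.37) and Nr0b1 (-0.36) were lower as well, though less so. Of the 33 expressed Sertoli markers, 10 were lowest and 16 highest in library 3. Whether preSertoli cells transcribe some of the Leydig genes themselves, or whether base composition shifted values in library 3, was not tested.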
